A study of Mus musculus with 20 samples.

How the data were processed

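Polyadenylated RNA from the hippocampus of 9-month-old male mice, labelled C57BL/6J, was measured in 20 libraries. The labels name 4 genotypes with 5 libraries each: PS19, PS19/C3aR KO, C3aR KO and WT. PS19 mice carry a transgene for human tau with a mutation that causes frontotemporal dementia, driven by the mouse prion protein promoter. C3aR, encoded by C3ar1, is the receptor for C3a, a fragment of complement component C3. Groups and replicate numbers were taken from the sample titles. The labels do not say that each library came from a separate animal, and they give no batch or date, so the p-values measure the spread between these libraries, which may in part be technical.

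Per the labels' protocols, RNA was extracted with RNeasy Mini columns, sequenced as 76-nt read pairs on an Illumina HiSeq instrument, aligned to mm10 with TopHat 2.0.9, and counted over the exons of each gene with htseq-count. The deposited files hold these counts as whole numbers for 24513 genes, with no normalization by the authors. DESeq2 is also named, per the submitters' processing notes, without a role. The strand setting and the annotation release are not given in the sources used here, so reads from overlapping genes on opposite strands cannot be told apart. Read pairs with more than 1 alignment were set aside by htseq-count, which can lower or split the counts of near-identical genes such as C4a and C4b, Gbp2b and Gbp2, the Serpina3 and H2 families and the Pcdhg cluster, whose members share exons.

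The 5 summary lines of each file name no gene and were left out of library sizes and tests. Pairs that met no annotated exon made up 17.4 to 25.4% of uniquely aligned pairs, with a mean of 21.7%, and pairs that met more than 1 gene made up 1.39 to 1.64%. Gene counts came to 33885800 to 47828100 per library. At this depth the median standard error of a log2 fold change between 2 genotypes was 0.097. Libraries of 1 group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 8.70 to 106, so no library was counted as a duplicate.

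All comparisons came from 1 edgeR 4.0.16 quasi-likelihood fit in R 4.3.3 to the 20 libraries with genotype as the only factor and TMM normalization. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16657 genes. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Standard errors of log2 fold changes were taken as the fold change over the square root of its F statistic. CPM are counts scaled to the TMM-normalized library size and are given as mean ± SD over 5 libraries per group. The comparisons were PS19 minus WT, C3aR KO minus WT, PS19/C3aR KO minus PS19, PS19/C3aR KO minus C3aR KO, and the interaction, which is the PS19 effect in the libraries labelled C3aR KO minus the PS19 effect in the others.

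The design, 43 gene lists for cell types and pathways, the rule for named genes and the alternative settings were fixed before the data were examined. Of these lists, 40 were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moved relative to all other genes. The same test was repeated with a correlation estimated from the data, and with fry, which asks whether the members moved on balance in 1 direction. The lists overlap: 14 members of the list of disease-associated microglia and 11 of the lysosome list also stand in other lists. The list of red blood cell genes had 1 tested member and was not tested, and the sex-linked and targeted-gene lists served as checks. A list score is the mean log2 CPM of the tested members (prior count 2) minus its WT mean.

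Named genes were C3ar1, Mapt and Prnp in every comparison; the 8 called genes with the highest and the 8 with the lowest log2 fold change at a mean log2 CPM of at least 1, leaving out predicted genes; up to 4 called members per list with the lowest p; and up to 15 genes called in both PS19 minus WT and PS19/C3aR KO minus PS19. Where fewer than 5 genes passed, the 5 with the lowest p were named. Gene positions are from a RefSeq table of GRCm38 (mm10), matched by symbol or synonym for 99.7% of tested genes. The C3ar1 exons are from GENCODE vM21 on the same build.

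The gene and list tests were tried on simulated counts for PS19 minus WT. These were made from the gene means over all 20 libraries and their library sizes, with changes set in the PS19 libraries. Over 16657 genes edgeR recovered 85% of 100 genes changed 2-fold and 64% of 100 changed 1.5-fold, and 8 of its 157 calls were unchanged genes. DESeq2 recovered 87% and 67% with 22 unchanged genes among 176 calls, and limma-voom 84% and 62% with 4 among 150. The camera tests and fry each recovered 10 of 10 changed lists and called 0 of 90 unchanged ones. The genes were simulated independently and the unchanged lists drawn at random. These counts therefore do not show how the preset correlation performs on lists whose members move together.

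The alternatives were DESeq2 size factors, upper-quartile normalization, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a stricter filter with a minimum count of 50, a fit to only the groups compared, the replicate number as a block, plain library sizes for levels, and leaving out each library in turn. The share of counts from Rn45s, a ribosomal RNA precursor, and the choroid plexus list score were added as covariates after seeing that they differed between libraries. Single values of libraries were compared by two-sided exact permutation tests, adjusted over 12 comparisons. Reads, sequence variants and the transgene sequence were not analysed here.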

Results

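Hippocampal gene expression was measured in 5 libraries each from WT mice, mice labelled C3aR KO, PS19 tau-transgenic mice and mice labelled PS19/C3aR KO, all 9 months old and male. Gene counts per library ranged from 33885800 to 47828100, with means of 37720800 in WT (SD 3072750), 40373600 in C3aR KO (SD 4320320), 38833100 in PS19 (SD 2590400) and 38955800 in PS19/C3aR KO (SD 5209280), n = 5 each. Between 18869 and 19321 genes had at least 1 count in a library. The sex-linked genes matched male tissue in all 20 libraries, with Ddx3y at 45.9 to 66.6 CPM and Xist at 0.148 to 0.966 CPM. The first principal component held 30.7% of the variance and the second 18.0%. Transthyretin (Ttr), the most abundant transcript of choroid plexus epithelium, varied widely within every group: 12.2 to 1899 CPM in WT, 9.53 to 3000 in C3aR KO, 38.6 to 4060 in PS19 and 15.1 to 3929 in PS19/C3aR KO. The share of gene counts from Rn45s, a ribosomal RNA precursor, averaged 3.59% in WT, 1.92% in C3aR KO, 1.85% in PS19 and 2.31% in PS19/C3aR KO.

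The targeted receptor gene was higher, not lower, in the libraries labelled C3aR KO. C3ar1 averaged 2.09 ± 0.286 CPM in WT, 16.0 ± 1.48 CPM in C3aR KO, 10.3 ± 3.43 CPM in PS19 and 17.0 ± 1.58 CPM in PS19/C3aR KO (SD, n = 5 each). No library of any other group came down to the WT range of 1.73 to 2.42 CPM, which rests on 65 to 93 counts per library. By edgeR the log2 fold change was 2.94 (SE 0.20, adjusted p = 9.51e-08) in C3aR KO minus WT and 2.31 (SE 0.20, adjusted p = 2.64e-06) in PS19 minus WT. It was 0.72 (SE 0.18, adjusted p = 0.0814) in PS19/C3aR KO minus PS19, or 0.55 with an adjusted p of 0.0157 without PS19 library 5, and DESeq2 gave an adjusted p of 0.009997 there. In PS19/C3aR KO minus C3aR KO it was 0.088 (SE 0.18, adjusted p = 0.947). C3ar1 lies on the minus strand of chromosome 6 from 122847138 to 122856161 (mm10). Exon 1, from 122855984 to 122856161, is untranslated, and exon 2, from 122847138 to 122851264, holds the 1431-nt coding sequence and a 3′ untranslated region of 2688 nt. The deposited counts are totals per gene, so they do not show which part of C3ar1 was read. The direction of C3ar1 goes against the C3aR KO label, and every direction below that involves these groups is that of the libraries labelled C3aR KO.

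Of the 2 genes to which transgene reads could add, Prnp was higher in both PS19 groups and Mapt passed in PS19 minus WT and not in PS19/C3aR KO minus C3aR KO. Prnp, the prion protein gene, whose promoter drives the transgene, averaged 887.9 ± 49.6 CPM in WT and 851.8 ± 19.3 in C3aR KO against 1885 ± 29.1 in PS19 and 1897 ± 81.3 in PS19/C3aR KO. It lies on chromosome 2 from 131909928 to 131938436. The log2 fold change was 1.09 (SE 0.044, edgeR adjusted p = 8.42e-12) in PS19 minus WT and 1.16 (SE 0.044, adjusted p = 2.75e-12) in PS19/C3aR KO minus C3aR KO, with all 5 transgenic libraries above all 5 others in both. Mapt, the mouse tau gene on chromosome 11 from 104229409 to 104332090, averaged 525.3 ± 27.8 CPM in WT and 617.9 ± 21.03 in PS19, a rise of 0.23 (SE 0.044, adjusted p = 0.00193). In PS19/C3aR KO minus C3aR KO its log2 fold change was 0.13 (SE 0.044, adjusted p = 0.303). The counts do not separate mouse reads from human ones.

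**Figure D1:**
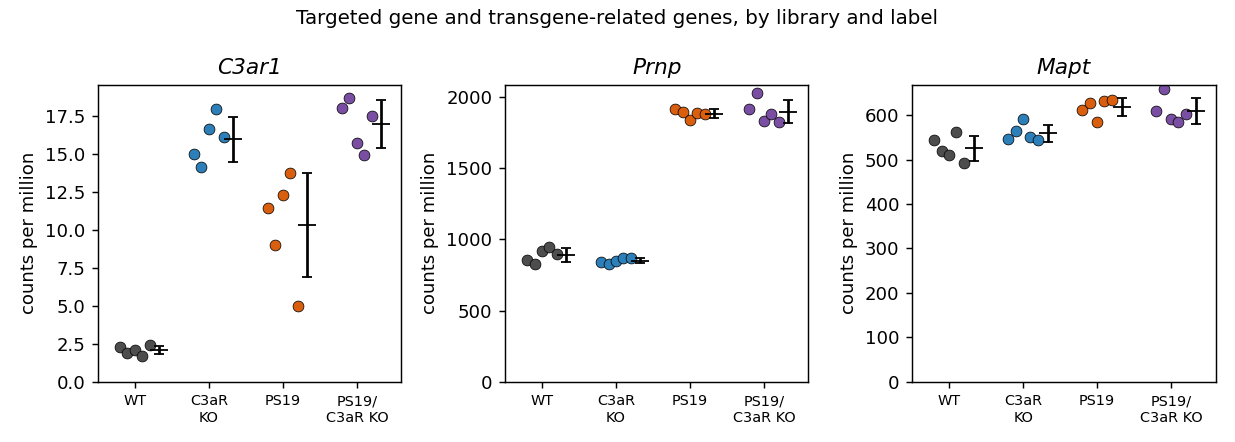
CPM of C3ar1, Mapt and Prnp in each library (points) by genotype label, with the mean and SD of 5 libraries. C3ar1 was lowest in WT, at 2.09 CPM against 16.0 in the libraries labelled C3aR KO, and Prnp was at 1885 CPM in PS19 and 1897 CPM in PS19/C3aR KO.

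The comparison of PS19 with WT asks what mutant tau changes in the hippocampus. Microglial genes rose broadly. Cst7 (cystatin F), Clec7a (the receptor dectin-1) and Itgax (the integrin CD11c), all known from microglia around protein deposits, rose by log2 5.40 (SE 0.62, edgeR adjusted p = 9.13e-05), 5.16 (SE 0.62, adjusted p = 0.000163) and 4.94 (SE 0.61, adjusted p = 0.000163). Cst7 went from 0.168 ± 0.067 to 7.11 ± 3.31 CPM. Trem2, a lipid-sensing receptor of microglia, rose by 1.68 (SE 0.24, adjusted p = 0.000279), from 9.64 ± 1.02 to 30.9 ± 9.82 CPM. Of 30 tested members of the list of disease-associated microglia 23 rose, or 26 adjusted over the list alone, with a median log2 fold change of 1.55 (camera adjusted p = 1.29e-45; adjusted p = 0.0131 with an estimated correlation). All 30 general microglial and myeloid genes rose, Cd53 by 1.37 (SE 0.18) and Ly86 by 1.81 (SE 0.23) among them, and all 30 also adjusted over the list alone (median 1.38, adjusted p = 1.21e-55; adjusted p = 0.0216 with an estimated correlation). Genes of resting microglia rose less: 12 of 16, or 14 adjusted over the list alone, with a median of 0.54 (adjusted p = 7.97e-13; adjusted p = 0.0349 with an estimated correlation). Among them the fractalkine receptor Cx3cr1 rose by 0.91 (SE 0.15) and the growth factor receptor Csf1r by 0.996 (SE 0.15). Of these 16 genes 4 passed with the Rn45s share as a covariate, where the list kept its camera call (median 0.45). For every gene named here all 5 PS19 libraries lay above all 5 WT libraries. PS19 library 5 had the lowest scores of its group for general microglia, pan-reactive astrocytes and the lysosome, and an Rn45s share of 3.65%, against 0.873 to 1.77% in the other 4 PS19 libraries and a mean of 3.59% in WT.

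Lysosomal and lipid-handling genes rose in PS19 as well. Of 26 lysosomal genes 24 rose, or 26 adjusted over the list alone (median 0.77, camera adjusted p = 7.72e-50; adjusted p = 0.0131 with an estimated correlation). The protease Ctsd rose by 1.28 (SE 0.16, edgeR adjusted p = 0.000163), from 336.9 ± 20.1 to 816.0 ± 198.3 CPM, and the hexosaminidase subunit Hexa by 0.75 (SE 0.095). Of 16 lipid and cholesterol efflux genes 9 rose, or 12 adjusted over the list alone (median 0.45, adjusted p = 5.33e-13; adjusted p = 0.0217 with an estimated correlation), including the lipid carrier Apoe by 0.63 (SE 0.10) and the exporter Abca1 by 0.96 (SE 0.15). Cholesterol synthesis went the other way. Of 22 genes 7 fell, or 11 adjusted over the list alone (median -0.24, adjusted p = 1.13e-08; adjusted p = 0.175 with an estimated correlation), among them Fdft1 by -0.42 (SE 0.094) and the regulator Srebf2 by -0.27 (SE 0.059). In the fit with the Rn45s share as a covariate the list kept its camera call (median -0.18) while 0 of the 22 genes passed; Fdft1 had -0.33 (SE 0.11, adjusted p = 0.116) and Srebf2 -0.21 (SE 0.068, adjusted p = 0.103), smaller folds with larger errors.

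Reactive astrocyte genes rose strongly in PS19. Gfap, the intermediate filament of astrocytes, went from 401.4 ± 80.8 to 2148 ± 749.5 CPM, a log2 fold change of 2.42 (SE 0.29, edgeR adjusted p = 0.000163), and vimentin (Vim) rose by 1.73 (SE 0.27, adjusted p = 0.000584). Of 13 pan-reactive astrocyte genes 11 rose, or 12 adjusted over the list alone (median 1.73, camera adjusted p = 4.70e-17; adjusted p = 0.0217 with an estimated correlation). Both subtype lists rose, A1 with 8 of 11 genes, or 9 adjusted over the list alone (median 0.82, adjusted p = 8.70e-09; adjusted p = 0.0454 with an estimated correlation), and A2 with 4 of 11, or 7 adjusted over the list alone (median 0.49, adjusted p = 3.29e-06; adjusted p = 0.0475 with an estimated correlation). General astrocyte genes had a median of 0.29 with 9 of 18 higher, or 15 adjusted over the list alone (adjusted p = 4.29e-10; adjusted p = 0.0682 with an estimated correlation), the water channel Aqp4 by 0.89 (SE 0.15). Of 28 genes of JAK-STAT3 signalling 15 rose, or 18 adjusted over the list alone (median 0.41, adjusted p = 1.33e-13; adjusted p = 0.0218 with an estimated correlation), including the oncostatin M receptor Osmr by 2.09 (SE 0.31) and Bcl3 by 2.72 (SE 0.42). All 5 lists kept their camera calls with the Rn45s share as a covariate, with medians of 1.55 for pan-reactive, 0.78 for A1, 0.53 for A2 and 0.20 for general astrocytes and 0.42 for JAK-STAT3 signalling, while the genes called were 5 of 13, 3 of 11, 3 of 11, 2 of 18 and 8 of 28.

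Complement, antigen presentation and cytokine genes rose with the glial genes. The 3 chains of C1q, which start the classical pathway, rose by 2.01 (C1qa, SE 0.26), 1.99 (C1qb, SE 0.23) and 1.93 (C1qc, SE 0.24), C4b by 2.33 (SE 0.32, edgeR adjusted p = 0.000257) and C3, the source of the ligand of C3aR, by 2.81 (SE 0.62, adjusted p = 0.00578), from 3.11 to 21.6 CPM. In total 10 of 23 complement genes other than C3ar1 rose, or 14 adjusted over the list alone (median 0.72, camera adjusted p = 6.53e-15; adjusted p = 0.0217 with an estimated correlation). Of 16 MHC class I genes 11 rose, or 14 adjusted over the list alone (median 0.66, adjusted p = 1.75e-13; adjusted p = 0.0475 with an estimated correlation). Of 7 MHC class II genes 3 rose, or 5 adjusted over the list alone (median 1.03, adjusted p = 5.28e-06; adjusted p = 0.0302 with an estimated correlation), Cd74 by 1.85 (SE 0.25). Of 27 cytokine and NF-kB genes 18 rose, or 20 adjusted over the list alone (median 0.99, adjusted p = 1.07e-18; adjusted p = 0.0302 with an estimated correlation), including the chemokine Ccl3 by 3.73 (SE 0.55). Of 26 interferon-response genes 23 rose, or 25 adjusted over the list alone (median 1.47, adjusted p = 1.18e-17; adjusted p = 0.108 with an estimated correlation), among them Ifit3 by 2.23 (SE 0.44), or 2.10 (SE 0.56, adjusted p = 0.0541) with the Rn45s share as a covariate. In that fit 1 of the 26 interferon genes, 3 of 16 MHC class I genes and 8 of 27 cytokine genes passed, while the 3 lists kept their camera calls, with medians of 1.40, 0.57 and 0.89.

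Oligodendrocyte genes were higher and synaptic genes slightly lower in PS19. Of 12 genes of disease-associated oligodendrocytes 10 rose, over all genes and adjusted over the list alone (median 1.19, camera adjusted p = 2.25e-13; adjusted p = 0.0131 with an estimated correlation). This list shares 8 members with other lists. Of 20 mature oligodendrocyte and myelin genes 8 rose, or 16 adjusted over the list alone (median 0.40, adjusted p = 1.60e-10; adjusted p = 0.205 with an estimated correlation), such as transferrin (Trf) by 0.91 (SE 0.17) and Cldn11 by 0.65 (SE 0.15). Of 28 synaptic genes 9 fell, or 13 adjusted over the list alone (median -0.18, adjusted p = 6.67e-09; adjusted p = 0.0454 with an estimated correlation). The postsynaptic scaffold Dlg4 changed by -0.23 (SE 0.047, edgeR adjusted p = 0.00333), from 896.0 ± 42.0 to 763.4 ± 35.4 CPM, and Rims1, which organises the presynaptic active zone, by -0.38 (SE 0.074, adjusted p = 0.00223). Of 14 dentate granule neuron genes 3 fell, over all genes and adjusted over the list alone (median -0.23, adjusted p = 0.00648; adjusted p = 0.381 with an estimated correlation), with Plk5 at -0.78 (SE 0.19, adjusted p = 0.0123), Trpc6 at -0.61 (SE 0.16, adjusted p = 0.0190) and Stxbp6 at -0.40 (SE 0.11, adjusted p = 0.0199). Trpc6 lost its call without WT library 5 (0.0579) or PS19 library 1 (0.0573) or 4 (0.0521) and Stxbp6 without PS19 library 2 (0.0535). In the list of 25 nuclear-encoded respiratory chain genes 3 fell, over all genes and adjusted over the list alone (median -0.083, adjusted p = 0.000114; adjusted p = 0.340 with an estimated correlation). These 5 lists kept their camera calls in the fit with the Rn45s share as a covariate, with medians of -0.25 for dentate granule neurons, -0.088 for the respiratory chain, -0.11 for synapse, 0.48 for mature and 0.96 for disease-associated oligodendrocytes. The genes called there were 0 of 14, 0 of 25, 2 of 28, 2 of 20 and 4 of 12. Plk5 had -0.82 (SE 0.23, adjusted p = 0.0661), Trpc6 -0.58 (SE 0.20, adjusted p = 0.128) and Stxbp6 -0.40 (SE 0.13, adjusted p = 0.108), so their calls ended with folds changed by less than 1 SE and errors 1.20 to 1.22 times as large.

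In 4 further lists the camera call in PS19 minus WT, at an adjusted p of 0.0435 in each, was lost without single libraries and in other fits. The list of CA1 pyramidal neurons had a median of -0.14 with 1 of 11 members called, Itpka at -0.39 (SE 0.069), and 1 adjusted over the list alone (adjusted p = 0.244 with an estimated correlation). Its call was lost without WT library 1 (adjusted p = 0.0521), 3 (0.0802) or 4 (0.0790) and without PS19 library 1 (0.0700), 4 (0.0615) or 5 (0.0565), with the Rn45s share as a covariate (median -0.13, 0.135) and with the stricter filter (0.0565). Ependymal genes had a median of 0.51 with 0 of 11 members called by edgeR, also adjusted over the list alone (adjusted p = 0.602 with an estimated correlation). Their call was lost without WT library 2 (0.346) or 4 (0.0632) and without PS19 library 1 (0.123) or 5 (0.208), and with the choroid plexus score as a covariate (median 0.23, 0.118). The unfolded protein response had a median of 0.14 with 3 of 20 members higher, or 4 adjusted over the list alone (adjusted p = 0.540 with an estimated correlation). It lost the call without WT library 1 (0.0623), 2 (0.128) or 4 (0.116) and without PS19 library 2 (0.190) or 4 (0.0994), and with the Rn45s share as a covariate, where the median was 0.033 (0.374). Cytosolic heat shock genes had a median of 0.12 with 1 of 12 higher, Bag3, and 1 adjusted over the list alone (adjusted p = 0.5999 with an estimated correlation). They lost it without WT library 1 (0.0623), 2 (0.211), 3 (0.0718) or 4 (0.0632) and without PS19 library 2 (0.544) or 5 (0.0536). With the Rn45s share as a covariate their median was 0.054 (0.216), and with the choroid plexus score the adjusted p was 0.0540.

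The other lists did not pass in PS19 minus WT. Choroid plexus genes had a median of 0.94 with all 16 members higher and 0 called (camera adjusted p = 0.145). The medians were 0.27 for border-associated macrophages (1 of 8 called, 2 adjusted over the list alone, camera adjusted p = 0.124), 0.41 for T and NK cells (2 of 8, 3 adjusted over the list alone, 0.0979) and 0.075 for the glucocorticoid response (3 of 14, 4 adjusted over the list alone, 0.0858). They were -0.066 for the circadian clock (2 of 14 lower, adjusted over the list alone 1 higher and 3 lower, 0.0858), 0.067 for immediate early genes (0 of 18, 0.808), 0.0046 for inhibitory neurons (1 of 20 higher, 0.745) and 0.11 for oligodendrocyte precursors (0 of 14, 0.184). Endothelial genes had a median of 0.0084 (0 of 20, 0.694), mural cells and fibroblasts 0.082 (0 of 17, 0.724), CA3 pyramidal neurons 0.0080 (0 of 12, 0.938) and ribosomal proteins 0.0036 (0 of 30, 0.662); for endothelial, CA3 and ribosomal genes camera ranked the list as lower although the median was above 0. Markers of neighbouring regions had medians of -0.027 for thalamus (0 of 14, 0.417), -0.11 for striatum (1 of 14 lower, 0.124) and -0.11 for cortical layers (0 of 14, 0.696). The 1 tested red blood cell gene, Alas2, had a log2 fold change of -0.017 (SE 0.36).

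In all, edgeR called 1803 of 16657 genes in PS19 minus WT, 1250 higher and 553 lower, and camera called 25 of 40 lists, 20 higher and 5 lower. Of the 25 lists 15 were also called with an estimated correlation and 20 by fry. The Rn45s share was lower in PS19 than in WT by 1.74 percentage points (difference -1.74, two-sided exact permutation p = 0.0317, adjusted p = 0.286 over 12 comparisons), and with it as a covariate, chosen after seeing the data, 431 genes were called, 374 higher and 57 lower, and 26 lists, 20 higher and 6 lower. In that fit all 1803 genes kept their direction, with a median size of 0.35 against 0.38, while the errors of all genes were 1.22 times as large in the median. The count was 1195 without WT library 4 and 1192 without PS19 library 3.

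**Figure D2:**
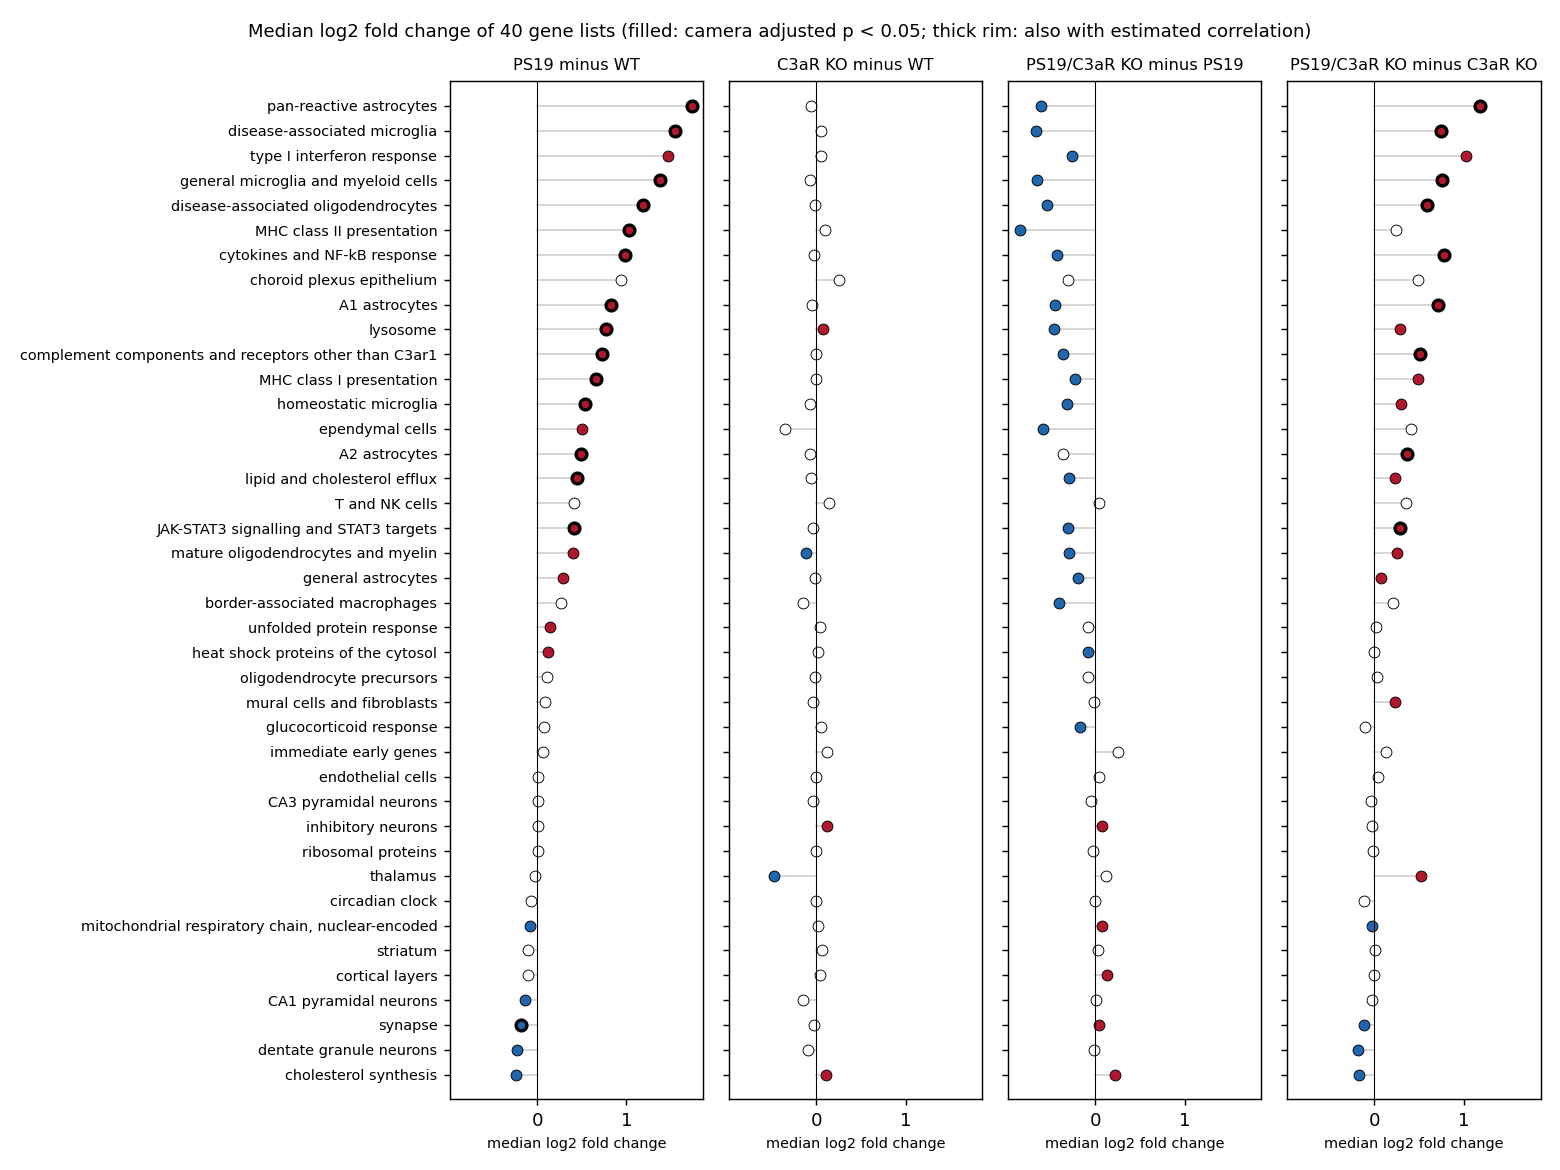
Median log2 fold change of the tested members of each gene list in each comparison. Filled points have a camera adjusted p below 0.05 and a thick rim marks those that also pass with an estimated correlation, which were 15 of 25 in PS19 minus WT and 0 of 25 in PS19/C3aR KO minus PS19.

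The comparison of C3aR KO with WT asks what the loss of the receptor does without tau, and few genes passed. Of 10 genes called by edgeR, 7 higher and 3 lower, 5 lie on chromosome 3. Gbp2b, which encodes a guanylate-binding protein, had 0 to 0.073 CPM in the WT libraries and 2.23 to 2.65 CPM in the libraries labelled C3aR KO, but also 2.18 to 12.02 CPM in PS19 and 2.74 to 8.75 CPM in PS19/C3aR KO. Its level relative to WT was 74.8-fold in C3aR KO (95% counting interval 34.1 to 204.8), 164.2-fold in PS19 (75.2 to 448.6) and 156.6-fold in PS19/C3aR KO (71.7 to 427.7), each resting on 6 WT counts in total and covering counting error only. Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, had a log2 fold change of -0.97 (SE 0.15, edgeR adjusted p = 0.00887), with 24.7 ± 4.31 CPM in WT and 12.6 ± 1.06 CPM in C3aR KO. Cryz, a quinone reductase, was higher by 0.41 (SE 0.059, adjusted p = 0.00497), at 17.9 ± 1.85 against 13.5 ± 0.338 CPM.

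Lamtor3, a scaffold protein of the lysosome surface, was higher in C3aR KO by 0.26 (SE 0.041, edgeR adjusted p = 0.0120) and Fam73a by 0.31 (SE 0.053, adjusted p = 0.0275). These 5 genes start at positions 123264801 (Sec24d), 137918555 (Lamtor3), 142594816 (Gbp2b), 152273459 (Fam73a) and 154596711 (Cryz) of chromosome 3 in mm10. Pcdhga4, of the gamma-protocadherin cluster whose members share exons, was higher by 0.73 (SE 0.088, adjusted p = 0.000516). Tubb6 had 0.71 (SE 0.12, adjusted p = 0.0276) and Kptn -0.39 (SE 0.069, adjusted p = 0.0300). Col6a4, at -2.17 (SE 0.37, adjusted p = 0.0276), was too low in level for the rule and was named after its values were seen. For all of these but Kptn, where 4 did, all 5 libraries labelled C3aR KO lay beyond all WT libraries, a count not taken for Col6a4. C3ar1 itself was the 1 called gene on chromosome 6. Besides C3ar1 and Gbp2b, 3 of the 10 genes also passed the same way in PS19 minus WT, which shares the WT libraries, as looked up after seeing the data. Tubb6 had 0.78 (SE 0.12, adjusted p = 0.000532) there and kept the call without any 1 library and with the Rn45s share, and Col6a4 had -1.64 (SE 0.36, adjusted p = 0.00640), or -1.42 (SE 0.40, adjusted p = 0.0691) with that share. Lamtor3 had 0.14 (SE 0.041, adjusted p = 0.0334), a call lost without WT library 3, 4 or 5 or PS19 library 3, 4 or 5 (adjusted p 0.0529 to 0.1006) and with the Rn45s share (0.12, SE 0.051, adjusted p = 0.211). The values in PS19/C3aR KO minus PS19 were 0.18 for Tubb6 (unadjusted p = 0.155), -0.59 for Col6a4 (0.140) and 0.10 for Lamtor3 (0.0251).

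Several of these calls were lost when 1 library was left out. Lamtor3 lost its call without C3aR KO library 5 (adjusted p = 0.0546). Fam73a lost it without WT library 3 or 5 or C3aR KO library 2, 4 or 5 (adjusted p 0.0521 to 0.0875), Tubb6 without WT library 1, 2, 4 or 5 or C3aR KO library 2, 3 or 5 (0.0536 to 0.0942) and Kptn without WT library 2, 3, 4 or 5 or C3aR KO library 1, 4 or 5 (0.0678 to 0.107). The count was 5 without C3aR KO library 5, 58 by DESeq2, 17 by limma-voom, 5 when only these 2 groups were fitted and 3 with the Rn45s share as a covariate. In the fit to 2 groups the folds were near those above, with 0.41 for Cryz (adjusted p = 0.135), 0.27 for Lamtor3 (0.142), 0.71 for Tubb6 (0.126) and -0.39 for Kptn (0.285). The Rn45s share was lower in C3aR KO than in WT (difference -1.67 percentage points, two-sided exact permutation p = 0.0476, adjusted p = 0.286), and with it as a covariate 6 calls of genes named by the rule ended with folds changed by less than 1 SE and errors 1.18 to 1.24 times as large: Sec24d at -1.06 (SE 0.18, adjusted p = 0.0536), Cryz at 0.38 (SE 0.071, adjusted p = 0.101), Fam73a at 0.34 (SE 0.063, adjusted p = 0.101), Lamtor3 at 0.25 (SE 0.050, adjusted p = 0.204), Kptn at -0.40 (SE 0.085, adjusted p = 0.230) and Tubb6 at 0.62 (SE 0.14, adjusted p = 0.4001). The call of Col6a4, a gene outside that rule, also ended in that fit.

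**Figure D3:**
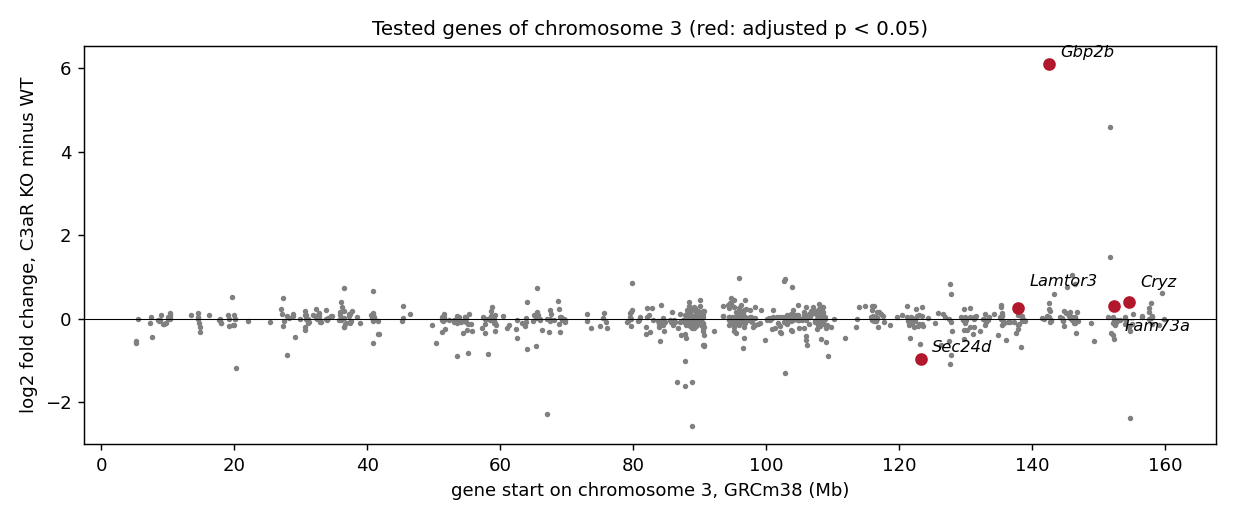
Log2 fold changes of the tested genes of chromosome 3 in C3aR KO minus WT by position (mm10), with the 5 called genes named. They lie between 123.26 and 154.62 Mb.

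Microglial and astrocyte lists did not pass in C3aR KO minus WT: the median was 0.050 for disease-associated microglia (camera adjusted p = 0.543), -0.073 for general microglia (0.660) and -0.054 for pan-reactive astrocytes (0.722). Camera called 5 lists, 3 higher and 2 lower, and 0 of the 40 with an estimated correlation (adjusted p = 0.974 for each) or by fry (0.931 for each). Thalamic genes had a median of -0.48 with 14 of 14 members lower (adjusted p = 1.85e-05; adjusted p = 0.974 with an estimated correlation), and inhibitory neuron genes 0.13 (adjusted p = 0.000156; adjusted p = 0.974 with an estimated correlation) with 2 members higher adjusted over the list alone. Cholesterol synthesis had 0.11 (adjusted p = 0.00112, or 0.151 without C3aR KO library 5; adjusted p = 0.974 with an estimated correlation). The lysosome list had 0.070 (adjusted p = 0.0223) and mature oligodendrocytes -0.11 (adjusted p = 0.0111), both with an adjusted p of 0.974 with an estimated correlation. The lysosome call was lost without WT library 2 (0.186) and without C3aR KO library 1 (0.118), 4 (0.190) or 5 (0.0577), and the oligodendrocyte call without WT library 1 (0.285) or 3 (0.300) and without C3aR KO library 2 (0.308) or 5 (0.772). Both were lost with the Rn45s share as a covariate, with medians of 0.045 and -0.043 (0.523 for each), and the oligodendrocyte call also with the choroid plexus score (median -0.0895, adjusted p = 0.0621). In the 5 called lists edgeR called 0 members over all genes, among 999 genes with an unadjusted p under 0.05. The number of called lists was 8 without WT library 5, 8 without C3aR KO library 1 and 3 without C3aR KO library 5.

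The comparison of PS19/C3aR KO with PS19 asks whether loss of the receptor alters the response to tau, and its direction is that of libraries whose C3ar1 counts go against the label. The genes with the lowest p were Zfp963, a zinc finger gene, at 0.73 (SE 0.10), Ltbp4, a binding protein of latent TGF-beta, at 0.42 (SE 0.060), and Fam198b, a Golgi protein, at 1.25 (SE 0.18), each higher in PS19/C3aR KO with an edgeR adjusted p of 0.00760. Coq2, an enzyme of coenzyme Q synthesis, was higher by 0.44 (SE 0.068, adjusted p = 0.0115). All 5 PS19/C3aR KO libraries lay above all 5 PS19 libraries for these 4 genes, whose calls were kept without any 1 library. With only the 2 groups fitted, Ltbp4 had 0.43 (adjusted p = 0.0528). Fam198b and Coq2 averaged 8.73 and 58.5 CPM in C3aR KO against 4.82 and 45.8 CPM in WT. Some called genes of this comparison lie near each other in mm10. Zfp963 and Zfp868 start at 69741639 and 69610654 of chromosome 8. Coq2, Selplg, Vps33a, Gusb and Lat2 start between 100654723 and 134600103 of chromosome 5. The other called genes named by the rule lie on other chromosomes. Whether these positions depart from chance was not tested, nor was a genome difference as their cause.

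Microglial, antigen-presentation and lysosomal genes were lower in PS19/C3aR KO than in PS19, with calls that were lost in several fits without 1 library. The chemokine Ccl6 had -1.57 (SE 0.27, edgeR adjusted p = 0.0275), with 4.51 ± 1.62 CPM in PS19 and 1.53 ± 0.734 CPM in PS19/C3aR KO. The MHC class II chaperone Cd74 had -1.28 (SE 0.25, adjusted p = 0.0361) and Clec7a -2.53 (SE 0.51, adjusted p = 0.0402). Of these, Ccl6 and Cd74 were lower in all 5 libraries than in every PS19 library, and Clec7a in 3. Ccl6 lost its call without PS19 library 1 (adjusted p = 0.0538) and without PS19/C3aR KO library 2 (0.0956), 4 (0.0556) or 5 (0.0773). Cd74 and Clec7a lost theirs without PS19 library 1, 2, 3 or 4 or PS19/C3aR KO library 2, 4 or 5, with adjusted p of 0.0575 to 0.0980 for Cd74 and 0.0604 to 0.130 for Clec7a. With only the 2 groups fitted the folds were near the same, at -1.56 for Ccl6 (adjusted p = 0.132), -1.275 for Cd74 (0.126) and -2.52 for Clec7a (0.203). With the Rn45s share as a covariate Ccl6 kept its call (-1.60, SE 0.28, adjusted p = 0.0479), Cd74 had -1.29 (SE 0.26, adjusted p = 0.0629) and Clec7a -2.165 (SE 0.55, adjusted p = 0.120).

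As lists, 21 of 30 genes of disease-associated microglia were lower adjusted over the list alone and 2 over all genes (median -0.67, camera adjusted p = 1.59e-21; adjusted p = 0.102 with an estimated correlation). For general microglia 27 of 30 were lower adjusted over the list alone and 0 over all genes (median -0.65, adjusted p = 5.59e-27; adjusted p = 0.137 with an estimated correlation). The lysosome list had 23 of 26 lower adjusted over the list alone and 1 over all genes, Gusb (median -0.46, adjusted p = 4.02e-24; adjusted p = 0.105 with an estimated correlation). MHC class II had 6 of 7 and 1 (median -0.85, adjusted p = 2.21e-06; adjusted p = 0.102 with an estimated correlation), and lipid efflux 9 of 16 and 0 (median -0.30, adjusted p = 1.19e-10; adjusted p = 0.102 with an estimated correlation). Homeostatic microglia had 7 of 16 and 1 (median -0.31, adjusted p = 8.26e-08; adjusted p = 0.182 with an estimated correlation). Choroid plexus genes had a median of -0.31 with 16 of 16 lower (adjusted p = 0.105) and ependymal genes -0.58 with 11 of 11 lower (adjusted p = 0.00168; adjusted p = 0.490 with an estimated correlation).

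Astrocyte lists were lower with few or no single genes called. General astrocytes had a median of -0.19 with 7 of 18 lower adjusted over the list alone (camera adjusted p = 1.92e-09; adjusted p = 0.161 with an estimated correlation), and pan-reactive astrocytes -0.61 with 0 of 13 (adjusted p = 6.31e-05; adjusted p = 0.322 with an estimated correlation). Complement genes had -0.36 with 8 of 23 lower and 1 higher adjusted over the list alone (adjusted p = 0.000396; adjusted p = 0.322 with an estimated correlation). Mature oligodendrocytes had -0.29 with 1 of 20 (adjusted p = 4.37e-09; adjusted p = 0.322 with an estimated correlation). Interferon genes had -0.26 with 0 of 26 (adjusted p = 0.0130; adjusted p = 0.724 with an estimated correlation), a call lost without PS19 library 2 (0.741), 3 (0.0638) or 4 (0.121) and without PS19/C3aR KO library 2 (0.127) or 5 (0.294). Cholesterol synthesis was higher in all 22 members with 0 called (median 0.21, adjusted p = 2.44e-09; adjusted p = 0.250 with an estimated correlation). Synaptic genes had 0.044 (adjusted p = 0.00930; adjusted p = 0.437 with an estimated correlation), a call lost without PS19 library 1 (0.0784) and without PS19/C3aR KO library 2 (0.0519) or 5 (0.0519).

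In all, edgeR called 42 genes in PS19/C3aR KO minus PS19, 12 higher and 30 lower, with 2416 genes at an unadjusted p under 0.05, while DESeq2 called 443, limma-voom 89, a fit to the 2 groups alone 10 and the fit with the Rn45s share 9. Without 1 library the count was 9 (PS19 library 1), 12 (PS19 2), 7 (PS19 3), 477 (PS19 5), 227 (PS19/C3aR KO 1), 8 (PS19/C3aR KO 2), 17 (PS19/C3aR KO 4) or 6 (PS19/C3aR KO 5). Camera called 25 of 40 lists, 5 higher and 20 lower, of which 0 passed with an estimated correlation and 9 by fry. Prnp was at 0.0091 (SE 0.043, adjusted p = 0.943) and Mapt at -0.019 (SE 0.044, adjusted p = 0.877).

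**Figure D4:**
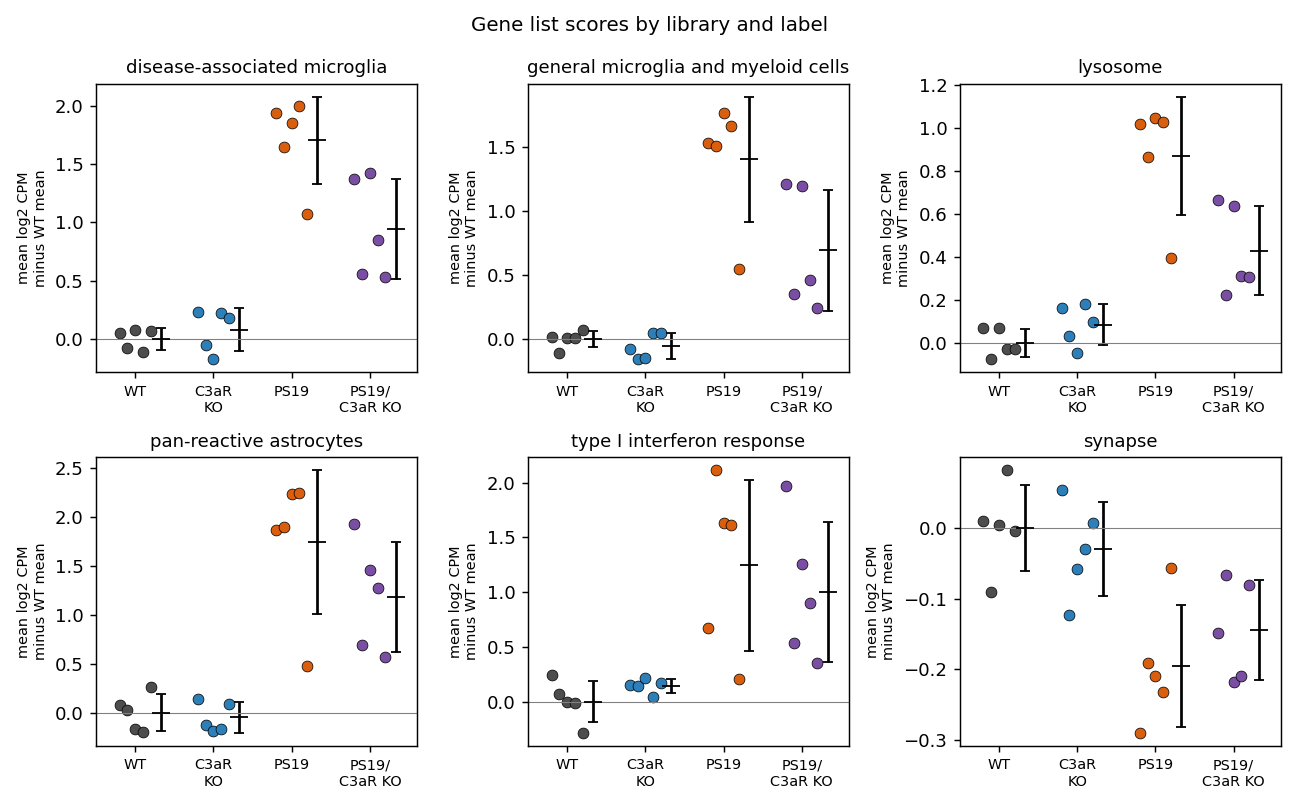
List scores of each library (points; mean log2 CPM of the tested members minus the WT mean) by genotype label, with the mean and SD of 5 libraries. The score for general microglia averaged 1.40 in PS19 and 0.69 in PS19/C3aR KO, with the lowest PS19 library at 0.55 and the highest PS19/C3aR KO library at 1.21.

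Most genes called in PS19 minus WT went the opposite way in PS19/C3aR KO minus PS19. This held for 1721 of 1803 genes (95.5%), and 25 of them passed in the second comparison. Both comparisons share the PS19 libraries, and with no C3aR KO effect simulated groups gave 65.4% (64.0 to 67.3% over 10 draws) with 0 passing. The draws called 2390 to 2568 genes in PS19 minus WT, against 1803. Each gene was drawn independently, which leaves out genes that move together between libraries, as many glial genes did in PS19 library 5. The simulated values therefore cannot decide whether the observed ones exceed chance. When genes were picked with some PS19 libraries and measured against the others, the share had a median of 90.3% over 10 splits, with a range of 63.2 to 94.5%. It was 87.9 to 94.5% where PS19 library 5 helped to pick the genes. Where that library was among those measured, the share was 63.2 to 79.0%. Across all genes, which are not independent replicates, the log2 fold changes had a correlation of -0.587 and a covariance of -0.0652, against -0.244 and -0.0238 in the simulation. Of genes higher in PS19, 23 were called lower in PS19/C3aR KO minus PS19, Ccl6, Cd74, Clec7a, Gusb and Il33 among them, against 2.25 for independent lists (n1 × n2 / N), a value that leaves out the shared PS19 libraries. Of genes lower in PS19, 2 were called higher, Ltbp4 and Vps33a, against 0.398 with the same limit. The number passing was 409 without PS19 library 5, 167 without PS19/C3aR KO library 1, 47 without PS19/C3aR KO library 3, 16 without PS19 library 4, 8 without PS19/C3aR KO library 4, 6 without PS19 library 2, 3 without PS19 library 3 and 2 without PS19 library 1 or PS19/C3aR KO library 2 or 5.

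The comparison of PS19/C3aR KO with C3aR KO gives the tau effect within the libraries labelled C3aR KO. Prnp was the 1 gene called by edgeR, at 1.16 (SE 0.044), and 1617 genes had an unadjusted p under 0.05. DESeq2 called 158 genes and limma-voom 1. The next genes by p did not pass: Gfap had 1.58 (SE 0.28), with 386.6 CPM in C3aR KO and 1153 ± 503.2 in PS19/C3aR KO, Cst7 3.25 (SE 0.59), the pentraxin Ptx3 2.53 (SE 0.45) and the lipopolysaccharide co-receptor Cd14 1.33 (SE 0.24), each with an adjusted p of 0.0724 and with all 5 libraries above all 5 C3aR KO libraries. Without PS19/C3aR KO library 2 or 5 these 4 genes passed, with adjusted p of 0.0238 to 0.0296 for Gfap, 0.0195 to 0.0211 for Cst7, 0.0259 to 0.0337 for Ptx3 and 0.0163 to 0.0337 for Cd14. DESeq2 gave 7.24e-05 for Gfap, 2.11e-05 for Cst7, 0.000130 for Ptx3 and 0.000207 for Cd14. The count was 68 without PS19/C3aR KO library 2, 2 without library 4 and 24 without library 5.

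By list, glial genes were higher in PS19/C3aR KO than in C3aR KO, with 0 members called over all genes by edgeR in each. General microglia had a median of 0.76 with 30 of 30 higher adjusted over the list alone (camera adjusted p = 4.10e-39; adjusted p = 0.0366 with an estimated correlation), disease-associated microglia 0.75 with 23 of 30 (adjusted p = 4.72e-29; adjusted p = 0.0272 with an estimated correlation) and pan-reactive astrocytes 1.18 with 11 of 13 (adjusted p = 7.29e-21; adjusted p = 0.0272 with an estimated correlation). Complement genes had 0.51 with 11 of 23 (adjusted p = 2.54e-14; adjusted p = 0.0274 with an estimated correlation) and cytokine genes 0.78 with 18 of 27 (adjusted p = 7.29e-21; adjusted p = 0.0309 with an estimated correlation). Interferon genes had 1.03 with 23 of 26 (adjusted p = 6.75e-22; adjusted p = 0.0712 with an estimated correlation) and the lysosome 0.29 with 18 of 26 (adjusted p = 9.34e-19; adjusted p = 0.0712 with an estimated correlation). Synaptic genes had -0.11 with 3 of 28 lower (adjusted p = 6.43e-09; adjusted p = 0.0521 with an estimated correlation). Thalamic genes had 0.52 with 13 of 14 higher (adjusted p = 0.000374, or 0.421 without PS19/C3aR KO library 4; adjusted p = 0.393 with an estimated correlation). Choroid plexus genes had 0.49 with 16 of 16 higher (adjusted p = 0.338). Camera called 22 lists, 18 higher and 4 lower, of which 9 passed with an estimated correlation and 15 by fry.

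The interaction tests whether the PS19 effect differed with the C3aR KO label. C3ar1, at -2.22 (SE 0.26, edgeR adjusted p = 0.00106), and Gbp2b, at -6.16 (SE 0.79, adjusted p = 0.00188), passed; both were low in WT alone, and the Gbp2b value rests on 6 WT counts. The next genes did not pass: Man2b2, a mannosidase, had -0.42 (SE 0.085, adjusted p = 0.578), and Moap1 and Serpina3h had 1.99 (SE 0.47) and -3.45 (SE 0.84), with adjusted p of 0.9995. By DESeq2 Man2b2 had an adjusted p of 0.0185, and without PS19 library 5 edgeR gave 0.0152 and 5 called genes. DESeq2 called 3 genes and limma-voom 2, and 691 genes had an unadjusted p under 0.05. Lysosomal genes had a median of -0.50, with 26 of 26 below 0 and 22 lower adjusted over the list alone (camera adjusted p = 3.50e-38; adjusted p = 0.0444 with an estimated correlation), and MHC class II genes -0.64 with 4 of 7 (adjusted p = 2.08e-07; adjusted p = 0.0444 with an estimated correlation). Disease-associated microglia had -0.81 with 11 of 30 (adjusted p = 4.95e-26; adjusted p = 0.0534 with an estimated correlation) and general microglia -0.62 with 0 of 30 (adjusted p = 7.29e-26; adjusted p = 0.160 with an estimated correlation). Pan-reactive astrocytes had -0.53 (adjusted p = 0.000440, or a median of -0.30 and 0.0844 with the Rn45s share as a covariate; adjusted p = 0.396 with an estimated correlation). Choroid plexus genes had -0.51 with 16 of 16 below 0 (adjusted p = 0.355). Camera called 24 lists, 5 higher and 19 lower, of which 2 passed with an estimated correlation and 0 by fry, whose lowest adjusted p was 0.0952.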

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

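All tests of explanations in this part were chosen after the results they bear on were seen, as were the fits with the Rn45s share or the choroid plexus score as a covariate.

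C3ar1 was higher in the libraries labelled C3aR KO than in WT, and its PS19 effect differed with that label (interaction log2 -2.22). An exchange of the C3aR labels as a whole would leave an intact gene that rises with the other microglial genes in PS19/C3aR KO minus C3aR KO. There C3ar1 lay -0.67 from the median of the general microglial list, more than 2 standard errors below it, which argues against that exchange. More microglia in C3aR KO is argued against by the median of that list, -0.073 against 2.94 for C3ar1. Reads from an altered C3ar1 allele that are still counted may set the level, since C3ar1 moved by only 0.088 (SE 0.18) between C3aR KO and PS19/C3aR KO while all 30 general microglial genes lay above it there and 2 of 30 did in PS19 minus WT; a biological rise of C3ar1 in mice with that label stays open and untested, because the counts do not show which exon was read.

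Of the 10 genes called in C3aR KO minus WT 5 lie on chromosome 3, against 0.483 for random positions (permutation p = 0.00254, 100000 draws), and at an adjusted p under 0.2 there were 11 of 36 against 1.74, which argues against chance positions. The Rn45s share was lower in C3aR KO (difference -1.67 percentage points, exact permutation p = 0.0476, adjusted p = 0.286), and with it as a covariate 3 genes were called, 1 of them, Gbp2b, on chromosome 3, while at an adjusted p under 0.2 there were 5 of 9 against 0.435 (permutation p = 0.00157). In that fit Sec24d went from -0.97 (SE 0.15) to -1.06 (SE 0.18), Cryz from 0.41 (SE 0.059) to 0.38 (SE 0.071), Lamtor3 from 0.26 (SE 0.041) to 0.25 (SE 0.050) and Fam73a from 0.31 (SE 0.053) to 0.34 (SE 0.063), so their calls ended with folds changed by less than 1 SE and errors 1.20 to 1.22 times as large. The paralog Gbp2, at -0.086 (SE 0.27) in C3aR KO minus WT, did not rise with Gbp2b. This argues against reads of a raised Gbp2 counted for Gbp2b there. It cannot exclude Gbp2 reads assigned to Gbp2b at an unchanged Gbp2 level. In PS19 minus WT Gbp2 rose with Gbp2b, by 1.56 (SE 0.27, edgeR adjusted p = 0.000982). A stretch of another strain's genome kept in the mice labelled C3aR KO is a candidate explanation: 4 of the 5 genes moved the same way with an unadjusted p under 0.05 in PS19/C3aR KO minus PS19, which shares no library. Gbp2b was the exception, at -0.063 there and -6.16 in the interaction, and it was also high in PS19 and low in WT alone. Sec24d was uneven within PS19. It had 24.5, 22.4 and 22.5 CPM in libraries 1, 2 and 4, but 14.2 and 13.7 CPM in libraries 3 and 5. Its range in C3aR KO was 11.4 to 13.8 CPM. For Gbp2b and Sec24d, levels near those of C3aR KO thus also occurred without that label. A stretch kept only with that label does not account for this. An effect of the receptor on the called genes of chromosome 3 stays open as untested.

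Microglial, astrocyte and lysosomal lists were lower in PS19/C3aR KO than in PS19. With the Rn45s share as a covariate the median of general microglia was -0.58, and with the choroid plexus score -0.69, against -0.65 without either. The camera call at the preset correlation was kept in both. For general microglia this argues against the Rn45s share or choroid plexus content as the whole cause. Other sides of RNA composition were not tested. The astrocyte and lysosome lists were not weighed in this way. Prnp, at 0.0091 (SE 0.043), argues against lower expression of the transgene. The C3aR genotype stays open, as do other genome differences that go with the C3aR KO label and the spread of gliosis between libraries. The share of neighbouring regions in the tissue was not weighed. Mean list scores in PS19 and PS19/C3aR KO were -0.050 and 0.16 for cortical layers and -0.10 and 0.070 for striatum. For thalamus they were -0.068 and -0.079. The lower lists are therefore consistent with an effect of the C3aR KO label but rest on 5 libraries per group, and 0 of them passed with an estimated correlation.

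Other divisions of the 10 libraries of a comparison into 5 and 5 were counted, in 60 drawn splits each, or 60 of the 20 libraries for the interaction, with the real one included. In PS19 minus WT 1 split, the real one, gave as many as 1803 genes, and the highest other gave 776. In C3aR KO minus WT 1 gave as many as 10, and the highest other gave 0. In PS19/C3aR KO minus PS19 2 gave as many as 42, the other calling 44. For the first 2 counts only the real split gave as many, a share under 0.05 taken by itself and with no adjustment over the comparisons. In PS19 minus WT this argues against chance for the count. In C3aR KO minus WT any 1 called gene, such as C3ar1, would have given the same share. The share therefore does not bear on the other calls there. For the third the share of drawn splits was under 0.05, but the other split called more genes than the real one. With 60 of 126 possible splits drawn and no adjustment over the comparisons, chance is not excluded for the third count. The first 2 counts carry these same 2 limits. In PS19/C3aR KO minus C3aR KO 10 splits gave as many as 1 gene and in the interaction 5 gave as many as 2, with 1749 and 509 as the highest. Chance is not excluded for the count in PS19/C3aR KO minus C3aR KO. The interaction splits shuffled the labels of all 20 libraries, which carries the PS19 effect into that contrast. They therefore cannot decide whether the interaction count exceeds chance. The split with 1749 genes points to a structure of the samples: it sets C3aR KO libraries 1 and 4 and PS19/C3aR KO libraries 1, 4 and 5, with choroid plexus scores of -1.09 to 2.68, against the others, at -3.09 to -1.89.

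Libraries far from the other 4 of their group were sought for 544 sets of gene levels, 160 of list scores and 12 of library measures, by the gap to the nearest library as a share of the group's range, with 0.71 as the limit. Chance gives about 1 in 20, or 27.2, 8 and 0.6, and 41, 9 and 2 were found. Of these, PS19 library 5 held 17 genes and 5 lists, always as the lowest. Its shares of the range were 0.731 for Gfap, 0.762 for C1qc, 0.837 for C1qa, 0.754 for Ctsz, 0.757 for Cd52, 0.757 for Cd53, 0.853 for Cd84, 0.742 for Ggta1, 0.727 for C4b, 0.831 for Trem2, 0.735 for Csf1r, 0.795 for Aspg, 0.786 for Bcl3, 0.746 for Tapbp, 0.805 for Ms4a7, 0.716 for Lat2 and 0.752 for H2-Oa. For the list scores they were 0.786 for general microglia, 0.786 for pan-reactive astrocytes, 0.734 for JAK-STAT3 signalling, 0.713 for cytokines and NF-kB and 0.721 for the lysosome. The Rn45s share of this library was 3.65%, at the WT mean of 3.59%, against 0.873 to 1.77% in the other 4 PS19 libraries.

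Of the other libraries 14 stood apart in 1 to 4 values each and 5 in 0. In PS19, library 1 was lowest for Kptn (0.736), library 2 lowest for Itpka (0.833) and highest for the heat shock list (0.864), and library 4 highest for Arsj (0.805) and lowest for Coq2 (0.787). In WT, library 1 was highest for Srgn (0.870) and lowest for Ccl5 (0.833), and library 2 lowest for Gfap (0.804), Cd9 (0.713) and the complement list (0.828) and highest for the cortical list (0.762). WT library 3 was lowest for Ltbp4 (0.738) and highest for Fam198b (0.798), library 4 lowest for Ifit3 (0.804), and library 5 highest for Itgax (0.769), Hexa (0.747), Trpc6 (0.738) and Sdf2l1 (0.717). In C3aR KO, library 2 was highest for Mt1 (0.7103), Mt2 (0.746) and Psmb9 (0.733), library 3 lowest for Clec7a (0.755), H2-Aa (0.720) and Pycard (0.717), and library 5 highest in gene counts (0.717). In PS19/C3aR KO, library 1 was lowest for Dnajb9 (0.805), library 3 lowest for Itpka (0.924) and highest for the striatum list (0.953), and library 4 highest for Il33 (0.723) and lowest in Rn45s share (0.711).

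In the interaction 24 lists passed the camera test of whether the PS19 effect differed with the C3aR KO label. The medians not given with the patterns above were -0.81 for disease-associated microglia, -0.22 for homeostatic microglia, -0.62 for general microglia, -0.17 for complement, -0.53 for pan-reactive, -0.25 for A1 and -0.23 for general astrocytes. They were -0.20 for JAK-STAT3 signalling, -0.37 for interferon, -0.21 for MHC class I, -0.64 for MHC class II, -0.32 for cytokines, -0.50 for the lysosome and -0.24 for lipid efflux. For the remaining lists they were 0.11 for cholesterol synthesis, 0.060 for synapse, -0.19 for mature and -0.57 for disease-associated oligodendrocytes, 0.50 for thalamus, 0.13 for striatum, -0.11 for the unfolded protein response, -0.14 for heat shock, 0.037 for the respiratory chain and -0.27 for the glucocorticoid response. Of the 24, lysosome and MHC class II passed with an estimated correlation (adjusted p = 0.0444 for both) and 0 passed by fry. With the Rn45s share as a covariate 9 lost the call: synapse (median -0.0029, adjusted p = 0.941), the unfolded protein response (-0.026, 0.904), cholesterol synthesis (0.040, 0.653), striatum (0.12, 0.320), MHC class I (-0.094, 0.190), A1 astrocytes (-0.17, 0.160), interferon (-0.16, 0.128), heat shock (-0.093, 0.101) and pan-reactive astrocytes (-0.30, 0.0844).

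Of the 20 fits to this interaction without 1 library, 11 lost the call of the unfolded protein response (adjusted p 0.0628 to 0.260), those without WT 1, 2 or 4, C3aR KO 2, 4 or 5, PS19 2 or 4 or PS19/C3aR KO 1, 2 or 3. Striatum lost it in 9 (0.0508 to 0.243), without WT 2, 3 or 4, C3aR KO 2 or 3, PS19 2, 3 or 4 or PS19/C3aR KO 3. Synapse lost it in 4 (0.0510 to 0.0852), without WT 4, C3aR KO 2, PS19 1 or PS19/C3aR KO 2. The A1 list lost it in 3 (0.0522 to 0.0679), without PS19 2 or 3 or PS19/C3aR KO 2, and the respiratory chain in 3 (0.0669 to 0.156), without C3aR KO 1, PS19 3 or PS19/C3aR KO 2. Mature oligodendrocytes lost it without WT 2 (0.0651) or C3aR KO 1 (0.0714), interferon and heat shock without PS19 2 (0.196 for both) and cholesterol synthesis without PS19/C3aR KO 2 (0.123). The other 15 lists kept the call in all 20 fits.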

How the results depend on the processing

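The fits with the Rn45s share or the choroid plexus score as a covariate were chosen after seeing the data, as were all fits to PS19/C3aR KO minus WT; the others were planned, and the cause was not tested for any change given here unless stated. Counts that moved by more than 1.5 times were, with the Rn45s share, 431 genes in PS19 minus WT, 3 genes and 8 lists in C3aR KO minus WT and 9 genes in PS19/C3aR KO minus PS19. DESeq2 gave 58 genes in C3aR KO minus WT, 443 in PS19/C3aR KO minus PS19 and 158 in PS19/C3aR KO minus C3aR KO, and limma-voom 17 and 89 in the first 2 of these. Fits to only the groups compared, with fewer samples, gave 5 and 10. With an estimated correlation camera called 15 lists in PS19 minus WT, 0 in C3aR KO minus WT, 0 in PS19/C3aR KO minus PS19, 9 in PS19/C3aR KO minus C3aR KO and 2 in the interaction, and fry called 0, 9 and 0 in C3aR KO minus WT, PS19/C3aR KO minus PS19 and the interaction.

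Leaving out 1 library gave 1192 to 2235 genes in PS19 minus WT, 5 to 13 in C3aR KO minus WT, 6 to 477 in PS19/C3aR KO minus PS19, 1 to 68 in PS19/C3aR KO minus C3aR KO and 2 to 5 in the interaction, and 3 to 8 lists in C3aR KO minus WT. The opposite-direction share stayed at 91.9 to 97.1%. Among named genes 1395 of these fits kept the call or its absence, 254 lost it, 10 gained it and 1 reversed, and among lists 1148 kept and 102 lost it. The reversed values were Prnp in PS19/C3aR KO minus PS19, a difference near 0, at -0.0018 with limma-voom and -0.015 without PS19/C3aR KO library 2 (-0.015 to 0.022 over all left-out libraries). Under the other settings 1446 values of named genes kept their side, 118 lost and 10 gained a call, 68 of the losses with the Rn45s share.

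The replicate number as a block gave 212 genes in PS19/C3aR KO minus PS19 and 22 in PS19/C3aR KO minus C3aR KO, and moved no other planned count of calls by more than 1.5 times. With it Gfap (adjusted p = 0.0201), Cst7 (0.0201), Ptx3 (0.0281) and Cd14 (0.0493) passed in PS19/C3aR KO minus C3aR KO. In PS19 minus WT the lists of CA1 neurons (0.0501), the unfolded protein response (0.0504) and heat shock (0.0589) and 4 named genes (0.0522 to 0.0594) did not pass with it, nor did border-associated macrophages (0.0592) and the glucocorticoid response (0.0600) in PS19/C3aR KO minus PS19. The block gave 305 genes in PS19/C3aR KO minus WT, against 179 without it, and an adjusted p of 0.0360 for Mamdc2 in C3aR KO minus WT. Of 30 pairs of libraries with the same number 16 had correlated deviations above 0.1, with a lowest r of -0.280. Their mean r was 0.134, against -0.034 for pairs with different numbers. Since 0 of 20 libraries correlated best with their own number in every other group, the numbers were not read as pairing samples. Some structure shared by number is not excluded. Depth, at 33885800 to 47828100 gene counts per library, limits genes near the floor, such as Gbp2b with 6 WT counts in total.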

Other observations

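The test of whether the PS19 effect recurs was written before its result was seen; the comparison of PS19/C3aR KO with WT, its settings, the genes named from it, Kptn in PS19/C3aR KO minus PS19, Mamdc2, Fam198b and Coq2 in C3aR KO minus WT, and the settings for these genes were chosen after seeing the data. By list, glial genes were higher in the libraries labelled PS19/C3aR KO than in WT, a pair of groups outside the planned comparisons. General microglia had a median log2 fold change of 0.72, with 3 of 30 members called higher by edgeR, or 28 adjusted over the list alone (camera adjusted p = 7.83e-25; adjusted p = 0.118 with an estimated correlation). Disease-associated microglia had 0.74 with 11 of 30, or 21 adjusted over the list alone (adjusted p = 1.59e-23; adjusted p = 0.0956 with an estimated correlation), and pan-reactive astrocytes 1.04 with 4 of 13, or 8 adjusted over the list alone (adjusted p = 2.63e-13; adjusted p = 0.0956 with an estimated correlation). These 3 camera calls were kept with the Rn45s share, whose mean was 2.31% in PS19/C3aR KO and 3.59% in WT, and without any 1 library. Camera called 22 lists there, and 0 with an estimated correlation.

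Calls of single genes in that comparison changed with the setting. By edgeR 179 genes were called, 98 higher and 81 lower, among 2538 with an unadjusted p under 0.05. The count was 20 with the Rn45s share, 374 with the choroid plexus score, 592 by DESeq2 and 507 by limma-voom. Without 1 library it was 65 (WT 1), 52 (WT 3), 41 (WT 4), 38 (WT 5), 45 (PS19/C3aR KO 1), 280 (PS19/C3aR KO 2), 28 (PS19/C3aR KO 3) or 101 (PS19/C3aR KO 4). The microglial genes Cst7, at 3.62 (SE 0.62), and Itgax, at 3.46 (SE 0.59), had an edgeR adjusted p of 0.0102 and kept the call without any 1 library, but had 3.54 (adjusted p = 0.0723) and 3.38 (0.0566) with the Rn45s share and 3.16 (0.0545) and 3.01 (0.0680) by limma-voom. Gfap had 1.52 (SE 0.28, adjusted p = 0.0173), or an adjusted p of 0.0528 without PS19/C3aR KO library 1, 0.0615 without library 3 and 0.110 with the Rn45s share (fold 1.41).

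The directions of the PS19 effect recurred in the libraries labelled C3aR KO, at a smaller size. Of 1803 genes called in PS19 minus WT, 1755 (97.34%) went the same way in PS19/C3aR KO minus C3aR KO, which shares no library with it, 892 of them with an unadjusted p under 0.05. The share lay above the 60% set beforehand, as a tau effect common to both C3aR labels would give. Many of these genes move together between libraries, so they are not independent. An uneven spread of gliosis between the 2 groups could give such a share as well. The share therefore cannot decide between these. The median size was 0.38 in PS19 minus WT and 0.18, signed by the first direction, in the second comparison, and 1780 genes were smaller in the second; genes picked for passing in the first tend to be smaller in any second comparison, so the size is not evidence of a weaker effect by itself.

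Cryz and Kptn passed both in C3aR KO minus WT and in PS19/C3aR KO minus PS19, which share no library, in the same direction; independent lists would share 0.00504 higher and 0.00540 lower genes. Cryz had 0.41 (SE 0.059, edgeR adjusted p = 0.00497) and 0.34 (SE 0.0585, adjusted p = 0.0275), and Kptn, which encodes kaptin, -0.39 (SE 0.069, adjusted p = 0.0300) and -0.42 (SE 0.069, adjusted p = 0.0214). In PS19/C3aR KO minus PS19 Cryz lost its call without PS19 library 1 or 3 or PS19/C3aR KO library 2, 4 or 5 (adjusted p 0.0528 to 0.0791), and Kptn without PS19 library 3 (0.0550) or PS19/C3aR KO library 5 (0.0666). In C3aR KO minus WT Kptn lost it in 7 of 10 fits without 1 library (0.0678 to 0.107), and both lost it, at nearly the same folds, with the Rn45s share (Cryz 0.38, SE 0.071, adjusted p = 0.101; Kptn -0.40, SE 0.085, adjusted p = 0.230) and with only the 2 groups fitted (0.41, adjusted p = 0.135, and -0.39, adjusted p = 0.285).

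Mamdc2, Fam198b and Coq2 passed in PS19/C3aR KO minus PS19 and not in C3aR KO minus WT. Mamdc2 averaged 7.54 CPM in WT and 9.66 in PS19 against 2.27 in C3aR KO and 2.50 in PS19/C3aR KO, with -1.96 (SE 0.37, edgeR adjusted p = 0.0322) in PS19/C3aR KO minus PS19, a call lost without PS19 library 1, 2 or 3 or PS19/C3aR KO library 2, 4 or 5 (adjusted p 0.0580 to 0.0980) and with the Rn45s share (-1.88, SE 0.38, adjusted p = 0.0650). In C3aR KO minus WT it had -1.73 (SE 0.37, adjusted p = 0.103), or an adjusted p of 0.00337 without C3aR KO library 4, 0.0458 with the choroid plexus score and 0.0476 by limma-voom. Fam198b had 1.25 and 0.86 (SE 0.18, adjusted p = 0.0968, or 0.00138 without WT library 3) in these comparisons. Coq2 had 0.44 and 0.35 (SE 0.068, adjusted p = 0.0530), with an adjusted p in C3aR KO minus WT of 0.0262 without C3aR KO library 1, 0.0431 without library 4 and 0.0293 with the choroid plexus score. By DESeq2 all 3 passed in C3aR KO minus WT, with 0.00146 for Mamdc2, 0.00242 for Fam198b and 0.000658 for Coq2.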
